A study of Drosophila melanogaster with 2 samples.

How the data were processed

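The measurement was ChIP-seq with an antibody against GFP on whole embryos (0 to 10 h) of a line expressing nom fused to GFP, in 2 biological replicates of 1 group, per the labels. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The authors deposited peak lists in narrowPeak format on dm6 and dm3. Per the deposited file descriptions, 1 list was called for each replicate and 1 on both replicates pooled, each against a control alignment and with background peaks kept as input for the irreproducible discovery rate (IDR), and an optimal list was thresholded by IDR from these. The aligner, the peak caller and the IDR cutoff are not given in the sources used here. The control library was not analysed here.

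Each peak's signal value was deposited by the authors as their peak caller gave it, and its scale is not given in the sources used here. It was used to rank and describe peaks within a list and to correlate the replicates by rank and by log2 value. Each peak also has a -log10 q value in the deposited lists, which has 1 value for all peaks of the optimal list (4.32 on dm6) and was not used for ranking. The summit position of each peak was also taken from the deposited lists. Read depth is unknown, so the precision of single signal values cannot be given. Intervals on shares of genes are exact binomial intervals that cover counting error only, and p-values over peaks or genes describe these 2 libraries.

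Positions on dm6 were joined to the Release 6 reference sequence and the Ensembl release of its annotation, whose arm names match after the chr prefix is removed, and all peaks lay within the arm lengths. Transposable element entries were left out. The annotation held 24111 distinct TSSs, 19630 of them of protein-coding genes. Peaks on dm3 were not joined to an annotation, and no coordinate was converted between builds. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

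An optimal peak counted as found in a replicate when a replicate peak overlapped it, and it took the value of the overlapping peak with the nearest summit. The strongest peaks of each replicate, as many as the optimal list holds, were also looked up in the other replicate. Promoter share, genomic class and replicate overlap were compared with 1000 circular shifts along each arm. Classes were assigned in the order promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, intron and intergenic. The tests, 20 gene lists, 13 motifs and most alternative settings were fixed before the data were examined, and 6 listed symbols were updated to those of the annotation. A gene had a promoter peak when a summit lay within 500 bp of any of its TSSs, and lists were compared with all other protein-coding genes by two-sided Fisher exact tests. Motifs and 7-mers were counted on both strands in 100 bp windows at summits and in flank windows 1000 bp to either side. Adjusted p-values are Benjamini-Hochberg values.

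The genes named are nom, the genes nearest to or holding the 20 strongest optimal peaks that were found in both replicates, and, per gene list, up to 4 members with the strongest promoter peaks and up to 2 members in alphabetical order without one. For 7-mers, the 10 with the largest odds ratio among those in at least 50 summit windows with an adjusted p below 0.05 are named. CG8202, cry, Lcp9, obst-B and the genes of fatty acid oxidation in the closing section were named after their values were seen. Alternatives covered the peak list (upper part by signal, each replicate alone), the TSS window (200 and 1000 bp) and set, the assignment of peaks to genes, the overlap rule, the control windows, the motif window (200 bp), soft-masked summits, the build and the ranking of strong and weak peaks.

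The statistics were tested on simulated data. A promoter share of 32.9% was recovered as 32.9%, a check of counting only, since the summits were placed with the same promoter definition. Of 100 unenriched sets of independent positions, 5 had p below 0.05. All 5 lists simulated with a raised share were found, as was 1 of 15 without. These lists were random genes, so they do not test lists whose members are neighbours and can share peaks. All 10 implanted 7-mers were found among 8192 tested, with 2 unrelated ones. Both window sets of that simulation came from flanks of the peaks. It therefore does not test calls that arise from a difference in composition between summits and flanks. A correlation of 0.8 was recovered as 0.801.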

Results

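Chromatin immunoprecipitation followed by sequencing was used to map the genomic sites recovered with nom (CG8145) in Drosophila melanogaster embryos. The transgenic line carried nom with GFP fused at its C-terminal end, and an antibody against GFP was used for the precipitation, per the labels. Whole embryos of mixed sex were collected from 0 to 10 h. The series held 1 group with 2 biological replicates, which the labels number 2 and 3. The files hold peak lists and no read counts, so the read depth of each library is unknown. No control library was analysed here, and the signal of each peak is the authors' own value.

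The optimal list on dm6 held 7273 peaks, which merged into 6731 separate regions covering 2.46 Mb. Peaks were 110 to 1885 bp wide, with a median of 381 bp. Their signal values ran from 130.7 to 7161, with a median of 218.3. Each of the 7273 optimal peaks was also in the pooled list of 30000 peaks, and they were its 7273 strongest. The list on the older build, dm3, held 7283 peaks.

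Most of the strongest peaks of 1 replicate were also among the strongest of the other. Of the 7273 strongest peaks of replicate 2, 78.9% overlapped one of the 7273 strongest of replicate 3, against a mean of 3.76% for 1000 circular shifts. In the other direction the share was 78.2% against 3.66% (one-sided permutation p = 0.000999 for both, the smallest these shifts can give). Looked up in the full list of the other replicate, the signals of these peaks correlated with a Spearman rho of 0.732 for peaks of replicate 2 and 0.740 for those of replicate 3, and a Pearson r of log2 signal of 0.794 and 0.788 (two-sided permutation p = 1e-04 for each, the smallest that 10000 resamples can give). These comparisons were added after seeing the data, since the optimal list was thresholded by IDR from the replicate and pooled lists and its overlap with the replicates is largely set by that choice. Of the 7273 optimal peaks, 7202 (99.0%) overlapped a peak in each replicate. The replicate lists of 30000 peaks include background. With at least 50% reciprocal overlap required, 70.3% of optimal peaks were covered by both. When each replicate list was limited to its 7273 strongest peaks, 78.1% were covered. Across the 7202 shared peaks, signal values correlated between the replicates with a Spearman rho of 0.674 and a Pearson r of log2 signal of 0.761 (two-sided permutation p = 1e-05 for both, the smallest that 100000 resamples can give), over peaks selected for agreement. All of these are correlations across peaks of 2 libraries, and peaks are not independent replicates.

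**Figure D1:**
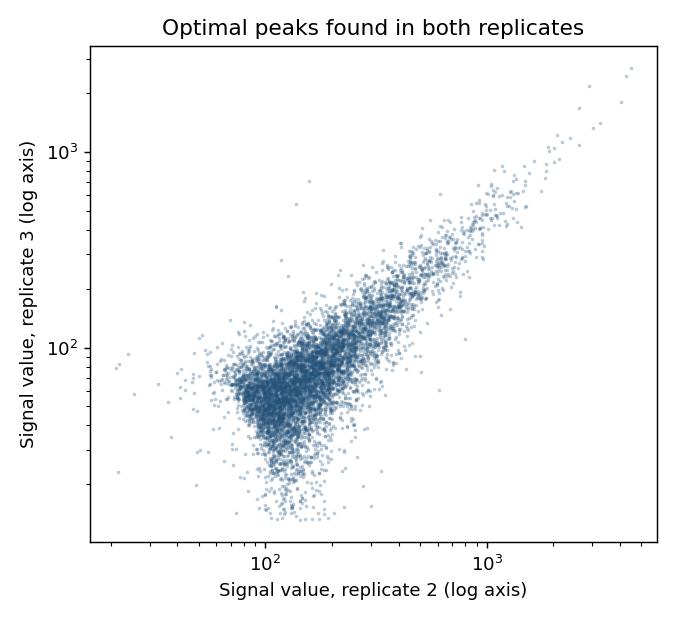
Signal value of each of the 7202 optimal peaks found in both replicates, with replicate 2 on the x axis and replicate 3 on the y axis, both log axes without a unit. Each point is 1 peak, and the points scatter most at low signal (Spearman rho 0.674, over peaks selected for agreement between the replicates).

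A small set of optimal peaks was found in 1 replicate. No peak of replicate 2 overlapped 34 optimal peaks, and no peak of replicate 3 overlapped 37. For 15 and 15 of these, respectively, the nearest summit of that replicate was more than 1000 bp away. The strongest lay 139 bp upstream of CG8202 on 3R (8731873 to 8732134, dm6), with a signal of 503.3 and rank 372 in replicate 2, while the nearest replicate 3 summit was 6801 bp away. It ranked 403 in the optimal list, and it is also the promoter peak of M1BP, which encodes a promoter-binding zinc finger protein. Another lay 284 bp upstream of cry, the cryptochrome gene of the circadian clock, with a signal of 258.4 in replicate 2 and the nearest replicate 3 summit 24001 bp away.

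The 20 strongest peaks found in both replicates had signals of 2532 to 7161. The peak ranked 2 lay at the promoter of yip2, which encodes a mitochondrial acetyl-CoA acyltransferase, on 2L (9914965 to 9915857, dm6, signal 6722). The peaks ranked 12 and 17 lay at the promoters of Mtpalpha (2L, 9576055 to 9576801, signal 3055) and Mtpbeta (2R, 23868045 to 23868782, signal 2715), the subunits of the mitochondrial trifunctional protein. The promoter of Cat, the catalase gene, carried the peak ranked 3 (3L, 18822487 to 18823281, signal 5852), and that of puc, a phosphatase gene of the JNK pathway, the peak ranked 8 (3R, 8105822 to 8106922, signal 3715).

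The strongest peak of the list (signal 7161) lay in an intron of dnr1 on 2R (22569640 to 22570872), 7682 bp from the nearest TSS, that of CG11362. The peak ranked 7 had its summit in the 3' UTR of Lsd-2, a lipid droplet protein gene, on X (15069164 to 15070267, signal 4351), and its nearest TSS was that of dob, a lipase gene, 2522 bp away. Summits in the 5' UTR were found at myo on chromosome 4 (694908 to 695783, signal 5085) and at cbt on 2L (478661 to 479511, signal 3548). Peaks at the promoters of CG8788 (signal 4657), Ugalt (3317), CG32772 (3276), CG43658 (2661) and hdly (2532) were among the 20 strongest. CG32772 also held an intronic peak (2930). Intronic summits lay in CG13204 (signal 3042), lncRNA:let7C (2951), the host transcript of let-7 complex microRNAs, and pdgy (2915), an acyl-CoA synthetase gene. Intergenic summits lay 1495 bp from CG43389 (signal 4364) and 706 bp from lncRNA:CR44713 (2565). Of these 20 peaks, 10 lay at promoters. All 20 were within the 100 strongest peaks of each replicate, with ranks no lower than 21 in replicate 2 and 26 in replicate 3.

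No peak was found at the tagged gene. nom (FBgn0037617) lies on 3R at 8723174 to 8725357, and the number of summits within 1000 bp of it was 0 in the optimal, pooled, replicate 2 and replicate 3 lists on dm6. The nearest optimal summit, the CG8202 peak, was 6595 bp away at 8731952. In replicate 3, the nearest summit was 7448 bp away, with a signal of 32.6 and rank 11716. The lists give only positions that were called, so signal below the calling level is not seen. The transgenic line was taken to carry an extra copy of nom, whose effect on peaks at or near nom was not tested.

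Summits were concentrated at promoters. Of the 7273 summits, 3682 (50.6%) lay within 500 bp of an annotated TSS, against a mean of 13.5% for 1000 circular shifts (range 10.9 to 15.9%, one-sided permutation p = 0.000999, the smallest these shifts can give). This was 3.74 times the shifted mean. With a TSS window of 200 bp it was 6.17 times (38.0 against 6.15%), and with 1000 bp 2.56 times (60.4 against 23.6%). Among the same number of weakest peaks of the pooled list, a comparison added after seeing the data, 18.7% lay at promoters (odds ratio 4.46 for optimal against weakest peaks).

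Summits in exons outside promoters were rare. Coding exons held 0.976% of summits against 13.7% for shifts (ratio 0.0714, and 0.0442 among peaks at or above the median signal), and 3' UTRs held 1.00% against 4.44%. Intergenic sequence held 10.8% against 27.3%, and introns held 35.5% against 40.2%. The intron class takes the remainder of each gene span, and 62 of its 2582 summits lay in an exon of a non-coding gene. For these 4 classes and promoters, the two-sided permutation p was 0.001998, the smallest these shifts can give, and 0.0024 after adjustment over 6 classes. For 5' UTRs, with 1.06% against 0.778%, the adjusted permutation p was 0.01998 and the ratio 1.36. Among the 3637 peaks at or above the median signal, the ratio was 1.35 and the call was lost with fewer peaks (adjusted permutation p = 0.110).

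**Figure D2:**
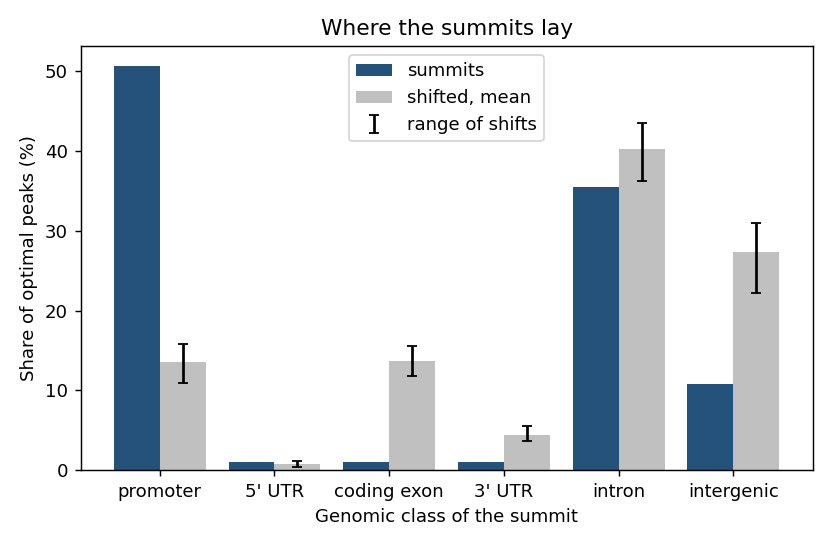
Share of the 7273 optimal summits in each genomic class in percent (dark bars), with the mean of 1000 circular shifts (grey bars) and their range (error bars). Promoters held 50.6% of summits against 13.5% for shifts.

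Genes for cytoplasmic ribosomal proteins carried promoter peaks most often among the 20 gene lists. Of 13968 protein-coding genes, 3410 (24.4%) had a summit within 500 bp of a TSS. Of 86 cytoplasmic ribosomal protein genes, 75 did (87.2%, exact 95% interval 78.3 to 93.4%, odds ratio 21.6, adjusted exact p = 1.58e-33). Signals were 917.7 at RpS4, 818.0 at RpS10b, 797.7 at RpL7 and 748.3 at RpS27, while RpL10Aa and RpL15 had no promoter peak. All p-values for gene lists are from two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 20 lists. In the restricted setting described with the next lists, adjustment was over the 16 that could be tested. Neighbouring members of a list can share a peak, so genes are not fully independent, as these tests and intervals take them to be. With each peak assigned to its nearest TSS, 7 lists passed, as in the main setting.

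The lists of heat shock, Notch pathway and chromatin factor genes also had higher shares. Of 16 heat shock and chaperone genes, 12 carried a promoter peak (75.0%, interval 47.6 to 92.7%, odds ratio 9.32, adjusted exact p = 0.000116). With the strongest peaks of replicate 3 alone, 10 did (odds ratio 5.05, adjusted exact p = 0.00522). The strongest were at Hsp83 (signal 1575) and Hsp27 (1219), followed by DnaJ-1 (593.3) and Hsp68 (559.5), while Hsp60A and Hsp70Aa had none. Of 17 Notch pathway and E(spl) complex genes, 11 carried one (64.7%, interval 38.3 to 85.8%, adjusted exact p = 0.00142), led by E(spl)mdelta-HLH (592.1), E(spl)m7-HLH (522.4), the ubiquitin ligase gene neur (432.0) and E(spl)mbeta-HLH (389.8). E(spl)m4-BFM and E(spl)m5-HLH had none. The Notch odds ratio was 5.69, and 3.78 with a TSS window of 200 bp (adjusted exact p = 0.0232). Of 34 Polycomb, Trithorax and insulator factor genes, 19 carried one (55.9%, interval 37.9 to 72.8%, adjusted exact p = 0.000275), led by Chro (1339), ph-p (1148), Cp190 (773.1) and M1BP (709.8, found in replicate 2 and not in replicate 3), while CTCF and Ibf1 had none. When list members and comparison genes were both restricted to genes with a pooled-list summit at a TSS, a setting added after seeing the data, these 3 calls were lost. Each optimal peak is also in the pooled list, so this restriction removes only genes without an optimal promoter peak, and it compares optimal with weaker promoter peaks. Odds ratios fell from 9.32 to 5.41 for heat shock (adjusted exact p = 0.0582), from 5.69 to 2.48 for Notch (0.336) and from 3.94 to 1.56 for chromatin factor genes (0.488), and the cytoplasmic ribosomal call was kept (adjusted exact p = 1.42e-16).

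Promoter peaks were rare at sensory receptor, cuticle and histone genes. None of the 179 genes of the odorant and gustatory receptor list had one (upper exact bound 2.04%, adjusted exact p = 2.18e-21), Gr10a and Gr10b among them. The name pattern of this list also takes in ionotropic receptor genes, whose symbols start with Ir. In the restricted setting, the receptor call was lost (6 genes left, adjusted exact p = 0.0582). Of 131 cuticle and chitin genes, 2 did (1.53%, odds ratio 0.0474, adjusted exact p = 9.81e-13), and Acp1 and Acp65Aa did not. With the strongest peaks of replicate 3 alone, 4 did (3.05%, odds ratio 0.0941, adjusted exact p = 9.34e-11). The odds ratio was 0.101 with peaks at or above the median signal and 0.105 in the restricted setting (adjusted exact p = 1.60e-05 and 0.00196). The 2 were Cpr51A (signal 283.7) and Cpr (691.8), and replicate 3 alone added Lcp9 and obst-B, named after the values were seen. Cpr encodes cytochrome P450 reductase and was taken in by the name pattern of the list. Of 116 histone genes, 4 did (3.45%, adjusted exact p = 6.23e-09): His3.3B (217.7), His4r (211.9), His3.3A (172.1) and His2Av (155.9). BigH1 and His1:CG31617 did not. No other histone gene was left in the restricted setting, which therefore gave no test of this list. Most histone genes are near-identical copies to which reads cannot be placed uniquely, so their count is uncertain.

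The other 13 lists did not pass the test. Shares were 30.1% of 73 mitochondrial ribosomal protein genes (signal 1499 at mRpL41, 1481 at mRpS23, 1472 at mRpS10, 933.5 at mRpL2 and none at mRpL1 and mRpL11), 29.2% of 48 proteasome genes (signal 257.3 at Rpt5, 237.8 at Rpn5, 216.7 at Rpn9, 191.6 at Rpn6 and none at Prosalpha1 and Prosalpha1R) and 25.0% of 84 respiratory chain and ATP synthase genes (signal 837.3 at ND-ASHI, 309.4 at SdhC, 304.4 at ATPsynbeta, 276.2 at ATPsynC and none at ATPsynB and ATPsynCF6). Adjusted exact p was 0.391, 0.625 and 0.946 for these lists. With each peak assigned to its nearest TSS, shares were 9.59, 16.7 and 20.2%, in that order, against 19.5% of other genes. Of the mitochondrial ribosomal protein genes, 7 then had a peak in place of 22, so most of those counted had no summit nearest to their own TSS.

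Among developmental lists, shares were 23.1% of 26 gap, pair-rule and segment polarity genes (signal 816.3 at hb, 471.2 at hry, 309.0 at oc, 266.0 at ci and none at Kr and btd) and 33.3% of 21 dorsal-ventral patterning genes (signal 490.1 at ush, 209.6 at rho, 200.2 at tup, 151.4 at vnd and none at Doc1 and Doc2). They were 26.3% of 19 neuroblast and neural genes (signal 1081 at elav, 389.6 at brat, 265.9 at grh, 198.0 at dpn and none at D and Poxn) and 6 of 20 mesoderm and muscle genes (signal 455.9 at tin, 184.7 at how, 182.7 at rols, 180.5 at sns and none at Act57B and Mhc). Adjusted exact p was 1, 0.425, 0.881 and 0.709, in that order. None of 8 Hox genes had a promoter peak, Abd-B and Antp among them (upper exact bound 36.9%, adjusted exact p = 0.327). With the strongest peaks of replicate 3 alone, 9 of 26 gap, pair-rule and segment polarity genes had one (odds ratio 1.60 in place of 0.929). Among peaks at or above the median signal, the odds ratio of this list was 1.97. In that setting, 1 of 21 dorsal-ventral genes (odds ratio 0.327 in place of 1.55) and 1 of 20 mesoderm and muscle genes (0.344 in place of 1.33) had a promoter peak.

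Maternal germ plasm and germline genes had peaks at 38.1% of 21 members (signal 436.7 at pum, 263.6 at orb, 248.1 at bgcn, 183.0 at BicD and none at AGO3 and BicC), and cell cycle and DNA replication genes at 34.2% of 38 (signal 268.5 at E2f1, 254.9 at Dp, 249.8 at RnrS, 247.7 at Mcm2 and none at Cdc6 and Cdk1). Shares were 6.67% of 15 pre-cellular zygotic genes (signal 255.2 at Sxl and none at CG14427 and CG16813), 8.33% of 24 testis and meiotic arrest genes (signal 177.8 at Mst87F, 133.5 at bol and none at Mst84Da and Mst98Ca) and 6.25% of 16 gut and fat body differentiation genes (signal 332.2 at fkh and none at Alp4 and Amy-p). Adjusted exact p was 0.327, 0.327, 0.282, 0.231 and 0.282, in that order. The testis list passed with the strongest peaks of replicate 3 alone (odds ratio 0.131 in place of 0.281, adjusted exact p = 0.0404). In that setting, 5 of the 21 maternal germ plasm and germline genes had a promoter peak (odds ratio 0.944 in place of 1.91).

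**Figure D3:**
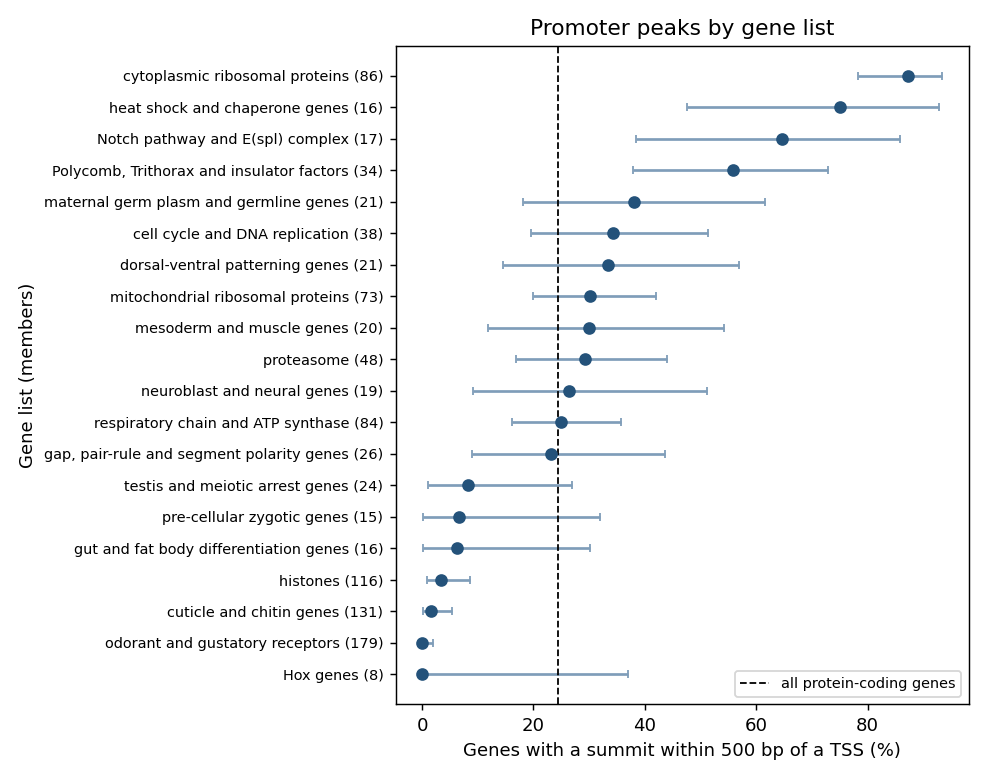
Percent of the members of each of 20 gene lists with an optimal summit within 500 bp of a TSS (points), with exact 95% binomial intervals (error bars). The dashed line marks the 24.4% of all protein-coding genes, and cytoplasmic ribosomal protein genes lie highest at 87.2%.

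GAGA repeats were enriched at summits, both at promoters and elsewhere, though most summit windows held no match. A GAGAGAG match, the type of sequence bound by GAGA factor, was found in 5.95% of the 100 bp summit windows against 2.06% of flank windows 1000 bp away (odds ratio 3.02, adjusted exact p = 1.03e-46, and 4.91 against GC-matched windows). At promoter peaks it stood at 6.74% against 1.60% at other TSSs (adjusted exact p = 2.03e-41), and at other peaks at 5.15% against 2.34% of flanks (adjusted exact p = 1.22e-12). Its matches were spread over about 200 bp either side of the summit. Motif p-values are from two-sided Fisher exact tests adjusted over 13 motifs.

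Core promoter sequences were also found more often than in flanks. Odds ratios were 5.72 for Ohler motif 1 (adjusted exact p = 2.68e-08), 2.56 for the Ohler motif 5 E-box (adjusted exact p = 0.000355), 2.14 for DRE (adjusted exact p = 0.000466), 1.68 for Ohler motif 7 (adjusted exact p = 1.72e-11), 1.22 for the Initiator (adjusted exact p = 8.53e-05) and 1.21 for the TATA box (adjusted exact p = 3.54e-05). Against other TSSs, promoter peaks had Ohler motif 7 more often (odds ratio 1.47, adjusted exact p = 8.14e-05) and the TATA box less often (odds ratio 0.783, adjusted exact p = 0.000214), while motif 1 (odds ratio 1.28, adjusted exact p = 0.396), motif 5 (1.09, 0.801), DRE (0.906, 0.751), the Initiator (0.974, 0.751) and Caudal-type matches (0.972, 0.714) did not pass. Caudal-type matches were higher (odds ratio 1.16, adjusted exact p = 2.36e-05) but not against GC-matched windows (odds ratio 1.05, adjusted exact p = 0.201), which also ended the TATA box call (odds ratio 1.07, adjusted exact p = 0.201) and raised the odds ratio of motif 5 to 4.64. Bicoid-type matches were lower (odds ratio 0.723, adjusted exact p = 0.000433). Zelda (odds ratio 0.665, adjusted exact p = 0.0625), CACGTG (0.858, 0.376), GATA (0.981, 0.632) and Ohler motif 6 (1.29, 0.594) did not pass. Zelda was lower with the strongest peaks of replicate 2 alone (odds ratio 0.503, adjusted exact p = 0.0022) and in 200 bp windows (0.701, 0.0125), and motif 6 was higher in 200 bp windows (odds ratio 2.00, 0.00384). GATA was lower at promoter peaks than at other TSSs (odds ratio 0.816, adjusted exact p = 0.000735). Windows at promoter peaks were centred on summits, up to 500 bp from a TSS. The other TSSs came from the 17383 without an optimal summit nearby. Comparisons with other TSSs therefore bear on sequence at summits and not on promoters as a whole.

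Outside promoters, the TATA box (odds ratio 1.25, adjusted exact p = 0.000792), Caudal-type matches (1.20, 0.000274) and GAGA passed against flanks. Ohler motif 7 (odds ratio 1.06, adjusted exact p = 0.681), motif 5 (1.85, 0.256), DRE (0.285, 0.0880), motif 1 (0, 0.291) and the Initiator (0.910, 0.291) did not. Over all peaks, GC-matched windows ended the TATA box and Caudal-type calls, and no such comparison was run outside promoters. Bicoid-type matches had an odds ratio of 0.782 there against 0.723 over all peaks, with fewer windows (adjusted exact p = 0.124). Among peaks at or above the median signal, DRE (odds ratio 1.53, adjusted exact p = 0.361), motif 5 (1.33, 0.621) and the Initiator (1.12, 0.204) no longer passed, motif 1 had 3.67 (0.0194), and the TATA box did not with the strongest peaks of replicate 3 alone (1.07, 0.154).

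**Figure D4:**
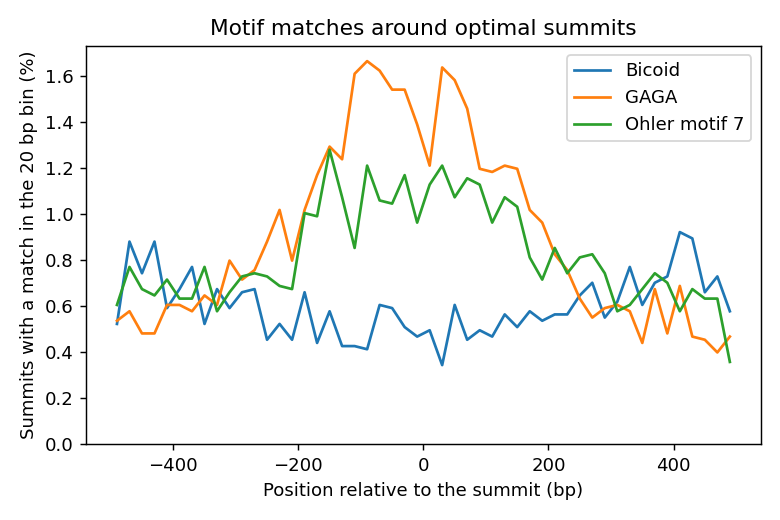
Percent of the 7273 optimal summits with a GAGA, Ohler motif 7 or Bicoid match in each 20 bp bin (y axis) by position from the summit in bp (x axis, 500 bp either side). GAGA reached 1.66% of summits in its highest bin, centred at -90 bp.

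Of 8192 7-mers tested, 507 were more frequent in summit windows than in flanks and 726 less frequent at an adjusted p below 0.05. Among peaks at or above the median signal, 249 were more frequent and 266 less. The 10 with the largest odds ratios each contained GAG or its complement CTC. They were CGCTCTC (odds ratio 3.77), CTCGCTC (3.07), AGAGAGC (3.04), CTCTCTC (3.02), CTCTCGC (2.78), AAGAGAG (2.70), AGAGAGA (2.67), AGAGCGC (2.60), AGAGCGA (2.58) and AGCGAGA (2.52).

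The promoter share of strong and weak peaks did not differ past the threshold. Of the 1454 strongest peaks, 48.5% lay at promoters against 47.7% of the 1454 weakest (odds ratio 1.03, adjusted exact p = 0.765, Fisher exact test, adjusted over 14 features). Shares were 50.9 against 47.2% between the 727 strongest and 727 weakest (adjusted exact p = 0.483) and 49.0 against 46.0% by mean replicate rank (adjusted exact p = 0.494). Caudal-type matches were more frequent in the strong peaks (36.2 against 24.7%, adjusted exact p = 2.82e-10), as was the TATA box (16.1 against 12.2%, adjusted exact p = 0.0133). Ohler motif 7 was less frequent (3.78 against 6.67%, adjusted exact p = 0.00416). GAGA matches did not pass (4.95 against 4.54%, adjusted exact p = 0.765). Strong and weak peaks were not matched on GC content, and over all peaks GC-matched windows ended the Caudal-type and TATA box calls. The TATA box call was lost when peaks were ranked by both replicates (15.8 against 13.8%, adjusted exact p = 0.494), and that of motif 7 between the 727 strongest and 727 weakest peaks (4.40 against 6.33%, adjusted exact p = 0.454). Between the 727 strongest and 727 weakest, the TATA box stood at 17.7 against 11.8% (adjusted exact p = 0.0131). Between the 3636 strongest and 3636 weakest, Caudal-type matches stood at 32.3 against 25.9% (adjusted exact p = 2.91e-08) and motif 7 at 4.18 against 5.61% (adjusted exact p = 0.0257). The Ohler motif 5 E-box passed in that comparison (0.275 against 0.743%, adjusted exact p = 0.0262).

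Summit density differed between chromosome arms (chi-square 44.5 over 6 arms, p = 1.80e-08). Density was 59.0 summits per Mb on X, 57.0 on 3L, 56.8 on 2R, 51.2 on 2L, 49.7 on 3R and 32.6 on chromosome 4, and no peak lay on Y. X had 1.11 times the density of the autosomes (1390 summits on X, two-sided binomial exact test p = 0.000702). With the strongest peaks of replicate 3 alone, the ratio was 1.06 (exact p = 0.0740). In the full lists with background, a comparison added after seeing the data, the ratio was higher, at 1.26 in replicate 2, 1.16 in replicate 3 and 1.28 in the pooled list.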

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

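Both tests of the ribosomal protein genes in this part, against other constitutive gene groups and by signal percentile, were chosen after the result was seen.

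The pooled dm3 list, which enters no comparison of the report, held 10 peaks on sequences outside the chromosome arms, a signal in data not otherwise reported on. Of these, 7 lay on XHet, with a strongest signal of 58.8 and a best rank of 16014 of 30000. The list includes background, and none of the 10 was in the optimal dm3 list. The dm3 list of replicate 2 also held 2 peaks on the mitochondrial genome, with a strongest signal of 141.1 and a best rank of 4071, which neither the pooled nor the replicate 3 list held.

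Genes for cytoplasmic ribosomal proteins carried promoter peaks at 75 of 86 members. Recovery alike at all constitutive promoters is argued against by the proteasome, mitochondrial ribosomal and respiratory chain lists, whose highest upper bound was 44.1%, below the lower bound of 78.3%. These lists were drawn by name pattern, so some members may not be expressed constitutively. Restricted to genes with a pooled-list summit at a TSS, their highest upper bound was 65.7%, below the cytoplasmic ribosomal lower bound of 89.2%. Recovery in proportion to transcription stays open, since no transcript levels or mock library were analysed here. The median ribosomal promoter peak lay at the 83.7th percentile of optimal signal, which such recovery could also give. No biological explanation was tested, since the design has 1 group.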

How the results depend on the processing

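Settings chosen after seeing the data are the restriction to genes with a pooled-list summit at a TSS, the lists matched on TSS number, leaving out Y genes, the weakest pooled peaks, 1 summit per merged region, the other lists at the tagged gene, the full lists on X and the strongest peaks of 1 replicate looked up in the other. Values for lists and motifs are odds ratios, except in matched lists, where they are observed over expected counts. Promoter share and the count of 0 at the tagged gene kept their direction or value under all alternatives run. Replicate agreement and coverage of optimal peaks did too, but that list was chosen by agreement, so only the direct comparison of the replicates bears on them. Of alternatives for values named in the design, 221 kept direction and side, 24 crossed to the other direction, 5 lost a call, 1 gained one and 5 counts moved by over 1.5 times. The cause of the changes was not tested, except that the peak count of 3637 at or above the median signal follows from that choice.

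With peaks at or above the median signal, 249 7-mers were higher and 266 lower, and odds ratios crossed 1 for respiratory chain (0.688), proteasome (0.284), gap and pair-rule (1.97), dorsal-ventral (0.327), cell cycle (0.770) and mesoderm (0.344) lists and for CACGTG (1.04). With 1 replicate left out, ranges were 0.882 to 0.978 for respiratory chain, 0.931 to 1.01 for proteasome, 0.939 to 1.60 for gap and pair-rule, 0.944 to 1.93 for maternal and 0.131 to 0.284 for testis, 5.05 to 9.42 for heat shock and 0.0480 to 0.0941 for cuticle lists, and 1.06 to 1.11 for the density on X against autosomes. With a TSS window of 200 bp, mitochondrial ribosomal (0.919) and gap and pair-rule (1.01) lists crossed 1, as did the neural list with 1000 bp (0.901). With each peak assigned to its nearest TSS, mitochondrial ribosomal (0.437) and proteasome (0.826) lists did.

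Restricted to genes with a pooled-list summit at a TSS, which removes only genes without an optimal promoter peak, 2 lists of 16 tested passed in place of 7. Odds ratios were 2.48 for Notch, 1.56 for Polycomb, 5.41 for heat shock and 0 for receptor lists, whose calls were lost. They crossed 1 for mitochondrial ribosomal (0.680), respiratory chain (0.521), proteasome (0.786), cell cycle (0.729) and neural (0.561) lists. Too few histone, Hox, zygotic and testis genes were left for a test. In matched lists, respiratory chain (0.953), neural (0.791) and mesoderm (0.744) lists crossed 1.

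Promoter peaks against other TSSs gave 5 motifs past the threshold in place of 9, and odds ratios crossed 1 for DRE (0.906), Ohler motif 6 (0.428), Initiator (0.974), TATA box (0.783) and Caudal (0.972). Other peaks alone gave 3 motifs, with DRE (0.285), Ohler motif 1 (0), Initiator (0.910) and GATA (1.12) across 1. GC-matched windows moved CACGTG (1.06) and GATA (1.01) across 1, and raised GAGA (4.91) and motif 5 (4.64), and 1 summit per region moved GATA (1.00). Between the 727 strongest and 727 weakest peaks, differences changed sign for DRE (0.138), GAGA (-0.825), Initiator (1.38) and GATA (0.413 points), and by mean replicate rank for GATA (0.625), while that of CACGTG became 0. The IDR 0.01 alternative was not run, since the lists hold no IDR score, nor was the tagged gene on dm3, since its position there was not matched. Unknown read depth limits statements on weak peaks and on sites not called. No paired analysis was possible because the series has 1 group.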

Other observations

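The list of fatty acid oxidation genes, the sequence CAAAGTCCA and the tests of GC content and of another tagged line were chosen after the strongest peaks and a first ranking of 9-mers had been seen.

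Genes of fatty acid oxidation carried promoter peaks at nearly every member examined. Of 26 genes, 24 had an optimal summit within 500 bp of a TSS (92.3%, exact 95% interval 74.9 to 99.1%). Examples below were picked after their values were seen. Signals reached 1769 at colt, a mitochondrial carnitine carrier gene, 1666 at Acadvl, 1583 at Etfb, 1421 at Mcad and 1041 at scu. The carnitine palmitoyltransferase gene whd had 594.4 and the peroxisomal gene Mfe2 687.9, while CPT2 and CG4594 had no promoter peak.

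The list was drawn up because yip2, Mtpalpha, Mtpbeta and Etf-QO (signal 2091, rank 27) stood among the strongest peaks, so chance naming of 4 such genes was a candidate explanation. Among the 22 other members, 20 carried a promoter peak against 24.3% of other protein-coding genes (odds ratio 31.2, two-sided Fisher exact p = 7.27e-11), which argues against it. Restricted to genes with a pooled-list summit at a TSS, which removes only genes without an optimal promoter peak, 20 of 21 did against 52.5% (exact p = 3.09e-05). Some members lie side by side, such as Acox57D-p and Acox57D-d, so the genes tested are not fully independent. A hypothesis is that the recovered sites favour this pathway, and whether nom itself is the protein that brings them stays untested.

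The sequence CAAAGTCCA, of the type bound by the nuclear receptor HNF4, was found in 91 summit windows (1.25%) against 0.138% of flank windows (odds ratio 9.20). Most of these windows, 66, lay outside promoters, where 1.84% had it (odds ratio 12.2) against 0.679% of promoter windows (odds ratio 5.59). Shares were 2.41% of the 1454 strongest peaks and 0.619% of the 1454 weakest. The differences between these groups of peaks were not tested. Of 2519 other orders of the same bases, 5 had an odds ratio as high or higher, up to 18.0, and since the sequence was picked by rank its place among them does not bear on its cause.

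The presence of CAAAGTCCA through GC content alone is argued against by an odds ratio of 8.001 against random windows matched on GC (95% interval 5.01 to 13.3, Fisher exact p = 2.78e-19 after multiplication by the 131072 9-mers it was picked from). Composition beyond GC stays open. For material of 1 replicate alone, odds ratios were 8.28 and 6.96 in the strongest peaks of replicates 2 and 3, so both held the sequence. These peaks largely overlapped those of the other replicate (78.9 and 78.2%). The test therefore had little room to come out otherwise, and no conclusion is drawn from it. Regions recovered for another protein or in another tagged line stay open, since no such library was analysed here, and the 2.41% of the strongest peaks with the sequence may come from either. No biological explanation was tested.

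Of the 30 optimal peaks with no summit of 1 replicate within 1000 bp, 2 lay within 50 kb of nom, where 6 of the 7273 optimal peaks lay. They were the peak at CG8202, found in replicate 2, and an intergenic peak at 8705698 on 3R, found in replicate 3 with a signal of 110.6, 1721 bp from the nearest replicate 2 summit.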
